A study of Mus musculus with 8 samples.

How the data were processed

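Gene expression was measured with single-channel oligonucleotide arrays in 8 RNA samples from the small intestine of BALB/c mice aged 6 to 9 days. The labels name 3 groups: ICC-DMP cells (3 samples), ICC-MY cells (3 samples) and tunica muscularis, the muscle coat of the gut wall (2 samples). In this field ICC stands for interstitial cells of Cajal, the pacemaker and neurotransmission cells of gut muscle, and DMP and MY stand for the deep muscular and the myenteric plexus; the labels print only the abbreviations. How the cells were isolated, how many animals gave a sample and their sex are not given in the sources used here. Per the labels' protocols, RNA was extracted with Trizol, purified on columns, and about 50 ng went through 2 rounds of amplification before biotin labelling.

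The deposited values are log2 expression values, 1 per probe set and array. RMA and limma are named in the submitters' processing notes, without versions and without saying which step each did. The file had 45101 probe sets. Values ran from 1.87 to 14.0 and array medians from 4.18 to 4.31, as values on a log2 scale do. The 99th percentile ran from 10.5 to 11.8 between arrays, so the arrays do not share 1 distribution. Whether they were normalized together is not known here. No further normalization and no filter on dim probe sets was applied. The 64 control probe sets were left out, which left 45037. Of these, 34945 named 1 gene in the platform annotation, 932 named several, and 9160 were not in that annotation and are unnamed here. The Entrez identifiers of 34741 of the single-gene probe sets were found in the mouse RefSeq gene table (assembly GRCm38.p6), which was used for symbols only; 0 symbols needed an update. Each of 18193 genes was represented by the probe set with the highest mean over the 8 arrays among those that named only that gene; 9010 genes had more than 1. Where a named gene passed and had several, another probe set also passed in the same direction for 36 of 56 genes in ICC-DMP against tissue, 45 of 73 in ICC-MY against tissue and 35 of 56 between the ICC classes, and 0 passed in the opposite direction. Etv1, Hcn4, Gapdh, Chrm2 and Itpr1 were among the listed genes with no probe set that named them alone, so they have no values.

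Groups came from the sample titles. Differences were fitted in R 4.3.3 with limma 3.58.1 (lmFit, contrasts.fit, eBayes), with all 8 arrays and 3 groups in 1 fit (residual degrees of freedom 5, prior degrees of freedom 3.17). The test was the 2-sided moderated statistic, adjusted by Benjamini-Hochberg over 18193 genes, and a gene passed at an adjusted p under 0.05. The 4 contrasts were ICC-DMP minus tissue, ICC-MY minus tissue, ICC-DMP minus ICC-MY, and the mean of the 2 ICC classes minus tissue. Every p printed with a gene or list is adjusted unless called unadjusted. Errors printed with a log2 difference are its standard error (SE) from that fit, unless called an SE over members. Those printed with a group mean are the SD over arrays. The number of arrays limits the precision, above all the 2 tissue arrays. The titles call the samples biological replicates but do not say whether they come from separate animals, so a p-value here measures a difference against the spread between samples.

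Before the data were examined, 24 gene lists were written down: ICC markers; smooth muscle contractile genes; enteric neuron, enteric glia and Schwann cell, macrophage, mast cell, lymphocyte, endothelial, pericyte, fibroblast and PDGFRA cell, mesothelial and intestinal epithelial markers; red blood cell, cell proliferation, immediate early and dissociation response, calcium handling and pacemaker candidate, neurotransmitter and paracrine signalling, gap junction and adhesion, potassium and chloride channel, MAPK feedback and ETV1 pathway, oxidative phosphorylation, glycolysis and hypoxia, cholesterol synthesis, and basement membrane and matrix genes. They held 399 entries, of which 372 were measured, covering 365 distinct genes. Each list was tested in each contrast with limma's camera (preset inter-gene correlation 0.01), adjusted over the 96 tests; camera with an estimated correlation and fry were alternatives. Members that passed were counted over all genes and adjusted over the list alone. Some ICC markers, among them Prkcq and Thbs4, may have become known from profiles of these same cells, so that list is not independent evidence of what the cells are. Genes were ranked only where the arrays of the compared groups did not overlap, without RIKEN, Gm, LOC, EST and clone names. The largest increases and decreases given below are those of this ranking. Of the ranked genes, the 10 largest called differences per direction between the ICC classes, and between their mean and tissue, plus the 3 largest of each class against tissue, were the genes to be named first. To these were added all ICC markers, up to 4 called members of every other list (or the 2 most abundant where 0 passed), and Kit, Ano1, Tacr1, Tacr3, Chrm2, Chrm3, Acta2 and Myh11 in every contrast; a named gene outside this rule is marked as chosen after its values were seen. Families of genes with a shared symbol stem (305 families, 610 tests) were screened afterwards.

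The 2 comparisons with tissue share their control arrays. Their overlap was set against 100 simulations of unchanged groups measured against the same controls, and against the number that independent lists would share. The 2 control arrays were not split, since each comparison would then have had a single control array.

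Replicate numbers were checked for pairing. After the group means were removed, all 7 same-numbered pairs of arrays correlated across genes at 0.155 to 0.608, while 2 of 14 pairs with different numbers exceeded 0.1 (range -0.61 to 0.169). Arrays with the same number thus varied together, but the 7 pairs are not independent, since the deviations of the 2 tissue arrays mirror each other. The pair of ICC-MY replicate 1 and tunica muscularis replicate 1 (0.577) also shares a narrow range of values. Whether the numbers mark shared samples or shared array quality cannot be told apart here, and the labels state no pairing. The planned fit without pairing was kept, and the number as a block was an alternative. Pairs of arrays of 1 group correlated at 0.978 or higher across genes, which are not independent replicates, and 0 pairs of arrays were identical.

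The fit was tested on simulated data in which 200 genes were shifted. At 4-fold it recovered 95.5% of them between the ICC classes, 92% for ICC-DMP against tissue, 89% for ICC-MY against tissue and 97.5% for the mean of both classes. At 2-fold these shares were 51.5%, 7.5%, 22.5% and 50.5%. Each was 1 random draw, and the 2 classes against tissue have the same median SE (0.217), so 7.5% and 22.5% do not show a difference in power. With 200 of 18193 genes shifted and independent noise, these shares are not the sensitivity in the real data. Between 2 and 12 unshifted genes were called. A contractile list shifted by 1 log2 unit was called by camera, and 0 of the other lists were.

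Alternatives tried were quantile normalization, centring each array on its median, leaving out probe sets under the 40th percentile of mean level, averaging a gene's probe sets, counting every probe set, array weights, eBayes with trend and robust settings, a threshold of 0.01, a minimum of 2-fold, the replicate block, fitting only the groups compared, and leaving out each array in turn. Leaving out 2 arrays with a narrow range of values was added after the data were seen. Probe sets naming several genes or none were tested in the count by probe set only. Raw array images were not used here.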

Results

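The arrays compared 2 classes of interstitial cells of Cajal with each other and each with the muscle coat they were taken from. There were 3 ICC-DMP, 3 ICC-MY and 2 tunica muscularis arrays, and array medians lay between 4.18 and 4.31. ICC-MY replicate 1 and tunica muscularis replicate 1 had a narrower range of values than the others (SD over probe sets 1.98 and 2.06, against 2.22 to 2.31). On both arrays, genes with a mean level of 10 to 12 read about 1 log2 unit below the other arrays of their group (-1.03 on each). The 3' minus 5' difference of the actin control was 4.66 in ICC-DMP replicate 3 and 4.28 in ICC-MY replicate 3, against 2.53 to 3.53 elsewhere. The Y-linked gene Eif2s3y read 2.30 in tunica muscularis replicate 1 and 8.01 in replicate 2, so the 2 tissue samples differed in Y-linked expression. It read 6.4 in ICC-DMP replicate 1 and 6.0 in ICC-MY replicate 1, so tissue replicate 1 also differed in it from the ICC samples of the same number.

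The comparison of the 2 ICC classes together with tissue asked what sets the isolated cells apart from the muscle coat. Kit, the receptor that marks these cells and that they need, averaged 11.09 ± 0.25 (SD, n = 3) in ICC-DMP, 11.74 ± 0.83 (n = 3) in ICC-MY and 7.82 ± 0.87 (n = 2) in tissue. The mean of both classes was higher by 3.60 (SE 0.45, adjusted p = 0.0011). Ano1, which encodes the calcium-activated chloride channel of their pacemaker current, was higher by 2.06 (SE 0.44, adjusted p = 0.0177, but 0.136 without tunica muscularis replicate 1). Transcripts of neurons, mesothelium and macrophages were far lower in the isolated cells than in tissue. Upk3b, a mesothelial gene, fell by 7.23 (SE 0.20), Vip, which encodes an inhibitory neuropeptide, by 6.72 (SE 0.28), and Csf1r, the macrophage growth factor receptor, by 4.78 (SE 0.34). Immediate early genes were far higher in the isolated cells, led by Fosb at 5.52 (SE 0.19, adjusted p = 1.74e-06).

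By limma, 2366 of 18193 genes differed between the mean of the ICC classes and tissue, 671 higher and 1695 lower, and 1610 of them by at least 2-fold. The split moved with the arrays and the unit: 305 were higher without tunica muscularis replicate 1 and 1139 without ICC-MY replicate 1. With every probe set counted, 3141 were higher and 2987 lower. The 10 largest increases were Fosb, Socs3 (4.70, SE 0.25), Jun (4.63, SE 0.38), Hspa1a (4.48, SE 0.38), Atf3 (4.45, SE 0.29), Egr1 (4.43, SE 0.31), Junb (4.17, SE 0.28), Gadd45b (4.07, SE 0.29), Usp53 (4.07, SE 0.59) and Zfp36 (3.87, SE 0.27). The largest decreases were those of the neuronal membrane gene Gpm6a (-7.43, SE 0.30), Upk3b, the fatty acid binding genes Fabp1 (-6.93, SE 0.88) and Fabp2 (-6.56, SE 0.88), the matrix gene Efemp1 (-6.88, SE 0.40) and Vip. Next came the synaptic gene Snap25 (-6.17, SE 0.25), Stmn2 (-6.04, SE 0.18), Calcb (-5.99, SE 0.18) and Tac1 (-5.92, SE 0.17), which encodes substance P. Fabp1 varied widely between the tissue arrays (9.15 ± 3.04, n = 2).

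Of 19 enteric neuron markers, 18 were lower in the ICC mean, and the same 18 when adjusted over the list alone (median -4.09, adjusted p = 2.1e-25, and 0.037 with an estimated correlation). All 10 mesothelial markers were lower, also when adjusted over the list alone (median -4.98, adjusted p = 2.97e-22, and 0.037 with an estimated correlation). Msln (-5.89, SE 0.16), Krt19 (-5.78, SE 0.16) and Lrrn4 (-5.56, SE 0.13) were examples. Among 16 macrophage markers 10 were lower, with Csf1r and Mrc1 (-4.25, SE 0.24) at the extreme. Adjusted over the list alone 12 were lower (median -1.32, adjusted p = 1.65e-10, and 0.037 with an estimated correlation). Lyz2 (-0.43, SE 0.28) and Laptm5 (-0.11, SE 0.78) did not pass, although Laptm5 did with its probe sets averaged (-0.96, adjusted p = 0.0224). These 3 lists were the only ones called under both forms of camera.

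Enteric glia and Schwann cell markers were lower for 4 of 8 members, 5 adjusted over the list alone, among them Fabp7 (-4.05, SE 0.43) and Erbb3 (-2.42, SE 0.16). That list passed with the preset correlation (median -1.22, adjusted p = 8.31e-05) and in fry (3.52e-05), but not with an estimated correlation (adjusted p = 0.0593). Of 13 intestinal epithelial markers 4 were lower, 6 adjusted over the list alone (median -0.86, adjusted p = 0.00901, but 0.616 with an estimated correlation and 0.0715 in fry). Of 19 proliferation genes 5 were lower, 14 adjusted over the list alone, including Ccna2 (-1.32, SE 0.19) and Mcm6 (-1.16, SE 0.21, adjusted p = 0.0547 without tunica muscularis replicate 1). The list's median was -0.73 (adjusted p = 1.64e-05, and adjusted p = 0.501 with an estimated correlation). Mki67 (-0.72, SE 0.29) did not pass, but did with the replicate block (-0.83, adjusted p = 0.0238), under quantile normalization (-0.81, adjusted p = 0.0032) and without the 2 narrow-range arrays (-0.92, adjusted p = 0.0083). Of 11 mast cell markers 0 passed in limma, with 1 at an unadjusted p under 0.05 (median 0.03, adjusted p = 0.969). Of 10 lymphocyte markers 0 passed in limma, with 0 at an unadjusted p under 0.05 (median 0.02, adjusted p = 0.311); the lymphocyte list was called as higher without tunica muscularis replicate 1 (adjusted p = 0.0206) and without the 2 narrow-range arrays (0.0383). Of 4 red blood cell genes only Alas2 was lower (-0.71, SE 0.14, adjusted p = 0.104 without tunica muscularis replicate 1), also when adjusted over the list alone, and the list was not called (median -0.19, adjusted p = 0.264).

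Immediate early and dissociation response genes were higher for 18 of 20 members in the ICC mean, and 18 adjusted over the list alone (median 3.66, adjusted p = 4.04e-25, and adjusted p = 0.0676 with an estimated correlation). The ICC are described as isolated cells, and how the tissue was handled is not given in the sources used here, so these genes do not separate cell identity from a response to isolation. Of 11 MAPK feedback genes 6 were higher, 8 adjusted over the list alone, among them Etv5 (2.50, SE 0.19), Phlda1 (2.19, SE 0.19) and Spry4 (1.79, SE 0.20). The list's median was 1.07 (adjusted p = 1.69e-07, and adjusted p = 0.0593 with an estimated correlation). Of 16 cholesterol synthesis genes only Mvd was higher (1.24, SE 0.22, adjusted p = 0.0575 without tunica muscularis replicate 1), also when adjusted over the list alone (median 0.25, adjusted p = 0.102). This list was called with the replicate block (adjusted p = 0.0212) and without ICC-DMP replicate 3 (0.0345).

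**Figure D1:**
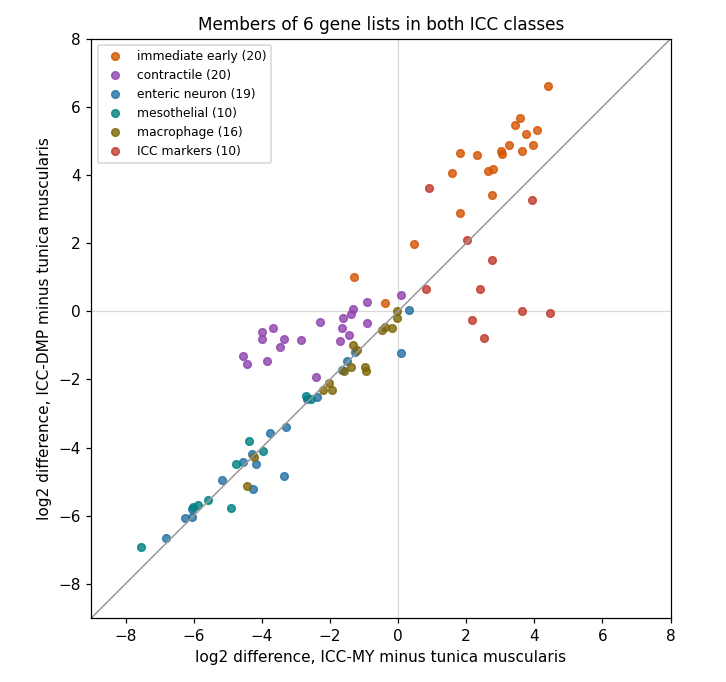
Each point is a gene of 1 of 6 lists, with its log2 difference from tunica muscularis in ICC-MY on the horizontal axis and in ICC-DMP on the vertical axis; the line marks equal differences. Neuron, mesothelial and macrophage genes lie near the line, 18 of 20 immediate early genes passed in ICC-DMP and lie above it, and contractile genes are spread along the horizontal axis (median -2.35 in ICC-MY and -0.66 in ICC-DMP).

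The comparison of ICC-DMP with tissue asked what marks the cells of the deep muscular plexus, which lie close to motor nerve endings. Thbs4, an extracellular matrix gene, was higher by 3.61 (SE 0.31, adjusted p = 0.000165), reaching 12.88 ± 0.09 (SD, n = 3) against 9.26 ± 0.16 (n = 2). Kit was higher by 3.27 (SE 0.50, adjusted p = 0.00366) and the potassium channel gene Kcnq5 by 5.09 (SE 0.27, adjusted p = 1.22e-05). Fosb (6.63, SE 0.22), Usp53 (6.05, SE 0.66) and Jun (5.68, SE 0.42) had the largest increases, and Gpm6a (-7.00, SE 0.34), Upk3b (-6.93, SE 0.22) and Fabp1 (-6.83, SE 0.98) the largest decreases. Contractile genes were closer to the tissue level than in ICC-MY, though lower for some members: Acta2 averaged 13.34 ± 0.20 (n = 3) against 13.41 ± 0.83 (n = 2), and neither it nor Actg2 (-0.61, SE 0.35) nor Myh11 (-0.80, SE 0.44) passed. Dimmer probe sets of Acta2 (-1.42, adjusted p = 0.00173) and Myh11 (-1.25, adjusted p = 0.0253) were lower. By limma, 2009 genes differed, 677 higher and 1332 lower, 1560 of them by at least 2-fold. Without tunica muscularis replicate 1, 395 were higher, and 427 and 445 without ICC-DMP replicate 1 or 2. With every probe set counted the majority turned, with 3223 higher and 2434 lower. Of all genes, 38.5% had non-overlapping arrays, against a chance share of 20% with 3 and 2 arrays.

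Of 10 ICC markers 4 were higher in ICC-DMP than in tissue, and 4 adjusted over the list alone: Kit, Thbs4, Ano1 (2.09, SE 0.49, adjusted p = 0.0305) and the fatty acid elongase gene Elovl6 (10.41 ± 0.07 against 8.91 ± 0.22, SE of the difference 0.37, adjusted p = 0.0369). The list passed with the preset correlation (median 0.65, adjusted p = 0.00414) but neither with an estimated one (adjusted p = 0.616) nor in fry (0.122), and part of it may rest on profiles of these cells. Cd44 (0.64, SE 0.31), Gja1 (0.66, SE 0.59), Edn3 (0.02, SE 0.42), Prkcq (-0.06, SE 0.47), Slc12a2 (-0.27, SE 0.52) and Cacna1h (-0.79, SE 0.38) did not pass. Cd44 did under quantile normalization (adjusted p = 0.0372), Slc12a2 as lower without the 2 narrow-range arrays (0.0422) and Cacna1h as lower with the replicate block (0.0106). Myh11 and Actg2 passed as lower than in tissue under quantile normalization (adjusted p = 0.00878 and 0.0116) and without the 2 narrow-range arrays (0.01 and 0.00771), and Actg2 also did with the replicate block (-0.72, adjusted p = 0.0496). The Ano1 call was lost without ICC-DMP replicate 1, 2 or 3 (adjusted p = 0.0822, 0.0995 and 0.0945) and without tunica muscularis replicate 1 (0.171). That of Elovl6 was lost without ICC-DMP replicate 1, 2 or 3 (0.117, 0.0984 and 0.107) without tunica muscularis replicate 1 or 2 (0.171 and 0.0846) and with arrays centred on their medians (0.0554). Without ICC-DMP replicate 1 the number of genes that differed was 1264, and without replicate 2 it was 1296.

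Of 20 contractile genes 6 were lower in ICC-DMP than in tissue, also when adjusted over the list alone, among them Cnn1 (-1.55, SE 0.26) and Casq2 (-1.45, SE 0.25). The list's median was -0.66 (adjusted p = 0.00343, and adjusted p = 0.662 with an estimated correlation), and the call was lost in fry (0.123) and without tunica muscularis replicate 2 (0.317). Of 12 endothelial markers Plvap was higher (3.36, SE 0.26) and 4 were lower, Vwf (-2.82, SE 0.27) and Esam (-2.57, SE 0.37) among them. The counts were the same adjusted over the list alone (median -0.45, adjusted p = 0.04, and adjusted p = 0.658 with an estimated correlation). This call was lost in fry (adjusted p = 0.115), with the replicate block (0.106), under quantile normalization (0.102) and with dim probe sets removed (0.36). It was also lost without the 2 narrow-range arrays (0.183), and without ICC-DMP replicate 2 or 3 (0.0678 and 0.0532), ICC-MY replicate 1 (0.0508) or tunica muscularis replicate 1 or 2 (0.114 and 0.0757). Glycolysis and hypoxia genes were higher for 4 of 17 members and lower for 1, the same adjusted over the list alone, led by Vegfa (2.24, SE 0.27) and the hexokinase gene Hk2 (1.62, SE 0.22). Their median was 0.23 (adjusted p = 0.0213, and adjusted p = 0.616 with an estimated correlation), and the call was lost in fry (0.221), under quantile normalization (0.103), without the 2 narrow-range arrays (0.0655) and without tunica muscularis replicate 1 (0.0582). Immediate early genes were higher for 18 of 20 members, 19 adjusted over the list alone (median 4.64, adjusted p = 7.72e-31, and adjusted p = 0.0593 with an estimated correlation). Atf3 (5.47, SE 0.32) and Socs3 (5.32, SE 0.28) were examples. Dusp4 (2.53, SE 0.42) and Etv5 (3.03, SE 0.21) were among 6 of 11 MAPK feedback genes that were higher. Adjusted over the list alone 7 were higher (median 1.17, adjusted p = 1.76e-06, and adjusted p = 0.0662 with an estimated correlation).

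The comparison of ICC-MY with tissue asked the same of the cells that pace the muscle from the myenteric plexus. Prkcq, which encodes protein kinase C theta, was higher by 4.46 (SE 0.47, adjusted p = 0.000446), averaging 11.38 ± 0.72 (SD, n = 3) against 6.92 ± 0.71 (n = 2). Kit was higher by 3.92 (SE 0.50, adjusted p = 0.00112), the endothelin gene Edn3 by 3.65 (SE 0.42, adjusted p = 0.000632) and the T-type calcium channel gene Cacna1h by 2.54 (SE 0.38, adjusted p = 0.0026). Icos, best known as a T-cell co-stimulatory receptor, had the largest increase (4.97, SE 0.42, adjusted p = 0.000121), ahead of Prkcq and Fosb (4.41, SE 0.22). The largest decreases were those of Gpm6a (-7.86, SE 0.34), Upk3b (-7.54, SE 0.22) and Efemp1 (-7.52, SE 0.45). Contractile genes were low. Cnn1 fell by 4.44 (SE 0.26), Myocd, the activator of the smooth muscle programme, by 4.54 (SE 0.29), Myh11 by 4.01 (SE 0.44) and Actg2 by 3.99 (SE 0.35). By limma, 2516 genes differed, 736 higher and 1780 lower, 1939 of them by at least 2-fold. Without tunica muscularis replicate 1, 411 were higher, 482 without ICC-MY replicate 2 and 1255 without ICC-MY replicate 1. With every probe set counted, 2681 were higher and 3010 lower. Of all genes, 34.2% had non-overlapping arrays, against a chance share of 20%. The count was 1520 when only these 2 groups were fitted.

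Of 10 ICC markers 8 were higher in ICC-MY than in tissue, 9 adjusted over the list alone: Kit, Prkcq, Edn3, Cacna1h, Elovl6 (2.76, SE 0.37), Cd44 (2.41, SE 0.31), Slc12a2 (2.17, SE 0.52, adjusted p = 0.0273) and Ano1 (2.03, SE 0.49, adjusted p = 0.0287). With a median of 2.47 the list passed with the preset correlation (adjusted p = 2.04e-09) and in fry (0.00794), but not with an estimated correlation (adjusted p = 0.253), and it is not independent evidence of what the cells are. Thbs4 (0.90, SE 0.31) and Gja1 (0.83, SE 0.59) did not pass; under quantile normalization both did (0.94 and 0.99, adjusted p = 0.016 and 0.00701). Thbs4 also did with array weights (0.0434) and without the 2 narrow-range arrays (0.0153). Ano1 no longer passed without ICC-DMP replicate 1, 2 or 3 (adjusted p = 0.0568, 0.0566 and 0.0512), ICC-MY replicate 2 or 3 (0.0834 and 0.0877) or tunica muscularis replicate 1 (0.155). For Slc12a2 these arrays were ICC-DMP replicate 1 or 2 (0.0567 and 0.0521), ICC-MY replicate 2 or 3 (0.0698 and 0.0778) and tunica muscularis replicate 1 (0.152). Both calls were also lost when only these 2 groups were fitted (adjusted p = 0.11 and 0.106). The ICC-DMP arrays enter this contrast only through the spread shared by the fit. Without any 1 of them the Ano1 difference stayed at 2.03.

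Of 20 contractile genes 16 were lower in ICC-MY than in tissue, 19 adjusted over the list alone (median -2.35, adjusted p = 7.22e-14, and adjusted p = 0.226 with an estimated correlation). Acta2 (-1.37, SE 0.43, adjusted p = 0.0762) did not pass, but did with the replicate block (-1.40, adjusted p = 0.00253), under quantile normalization (0.000686), with averaged probe sets (0.0017) and without the 2 narrow-range arrays (0.0039). Fibroblast and PDGFRA cell markers were lower for 7 of 14 members, 9 adjusted over the list alone, such as Pdpn (-1.36, SE 0.20). Their median was -1.24 (adjusted p = 4.82e-05, and adjusted p = 0.354 with an estimated correlation). Pericyte markers were higher for 2 of 7 members, Pdgfrb (3.37, SE 0.36) and Notch3 (1.80, SE 0.21). Adjusted over the list alone 3 were higher and 1 lower, and the list was not called (median 0.48, adjusted p = 0.0613). It was called with dim probe sets removed (0.0338) and without ICC-DMP replicate 3 (0.049), ICC-MY replicate 1 (0.0217) or tunica muscularis replicate 2 (0.0199). Gap junction and adhesion genes were higher for 1 of 16 members and lower for 5 (7 adjusted over the list alone), among them Alcam (-4.67, SE 0.21), Cdh2 (-3.86, SE 0.21) and Cadm1 (-3.66, SE 0.31). The median was -0.42 (adjusted p = 0.00807, but 0.285 with an estimated correlation and 0.0578 with averaged probe sets). Oxidative phosphorylation genes had a median of 0.52 and passed as a list (adjusted p = 0.000953, and adjusted p = 0.716 with an estimated correlation), although limma called 0 of 29 members, 3 at an unadjusted p under 0.05. The list was no longer called in fry (adjusted p = 0.48) and without tunica muscularis replicate 1 (0.183). MAPK feedback genes were higher for 8 of 11 members and lower for 1, also when adjusted over the list alone (median 1.42, adjusted p = 7.01e-06, and adjusted p = 0.0728 with an estimated correlation). Spry1 (2.91, SE 0.31) and Phlda1 (2.83, SE 0.21) were the highest. Of 20 immediate early genes 17 were higher (median 2.91, adjusted p = 7.34e-17, and adjusted p = 0.123 with an estimated correlation). Adjusted over the list alone 17 were higher and 2 lower.

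The 2 classes shared 242 genes higher than tissue, where independent lists would share 27.4, and 1012 lower, where independent lists would share 130. With the replicate block they shared 371 higher and 1388 lower. The shared increases numbered 117 without tunica muscularis replicate 1, 144, 148 and 157 without ICC-DMP replicate 1, 2 or 3, 152 without ICC-MY replicate 2 and 358 without ICC-MY replicate 1. Snap25, Vip, Upk3b and Stmn2 were among the shared decreases, and Fosb, Socs3 and Kit among the shared increases. In simulations of unchanged groups with the same controls the overlap was 0, but such groups yield almost no calls, so this does not measure what shared controls add. Across genes, which are not independent replicates, the covariance of the 2 differences was 0.413 against a simulated 0.0416. Their correlation was 0.66, and 0.60 in these simulations (highest 0.61). The simulated correlation follows from the numbers of arrays whatever the spread, so setting the 2 beside each other does not measure what shared controls add. The covariance exceeded its simulated value by 0.371, with noise simulated as independent between arrays. The 2 comparisons use the same 2 tissue arrays, which were not split, so part of the excess in shared calls may come from the shared controls. In 103 genes the classes differed from tissue in opposite directions: 80 were higher in ICC-DMP and lower in ICC-MY, and 23 the reverse.

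The direct comparison of ICC-DMP with ICC-MY asked how the pacemaker and the neurally coupled class differ. The glutamate receptor gene Gria1 averaged 8.87 ± 0.04 (SD, n = 3) in ICC-DMP and 3.95 ± 0.32 (n = 3) in ICC-MY, a difference of 4.92 (SE 0.18, adjusted p = 6.95e-06). The homeobox genes Irx3 (4.52, SE 0.17) and Irx5 (4.53, SE 0.23), the neural adhesion gene Ncam1 (4.02, SE 0.20) and Kcnq5 (4.30, SE 0.24) were also higher in ICC-DMP. In the other direction, the desmosome gene Dsp (-5.24, SE 0.39), the Wnt inhibitor gene Dkk2 (-5.23, SE 0.48), Icos (-5.14, SE 0.37) and Prkcq (-4.52, SE 0.42, adjusted p = 0.000316) were higher in ICC-MY. By limma, 1577 genes differed, 976 higher in ICC-DMP and 601 higher in ICC-MY, 1224 of them by at least 2-fold. Of all genes, 25.6% had non-overlapping arrays, against a chance share of 10%. Under quantile normalization the split was 1281 higher in ICC-DMP and 1277 higher in ICC-MY, and without the 2 narrow-range arrays it was 1228 and 1402. With each array centred on its median it was 918 and 504. The larger number on the ICC-DMP side thus held under centring, was nearly even under quantile normalization and turned without the 2 narrow-range arrays. With the replicate block 2617 genes differed (1597 and 1020). Without ICC-DMP replicate 1 the count was 991, and without ICC-DMP replicate 2 it was 996.

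**Figure D2:**
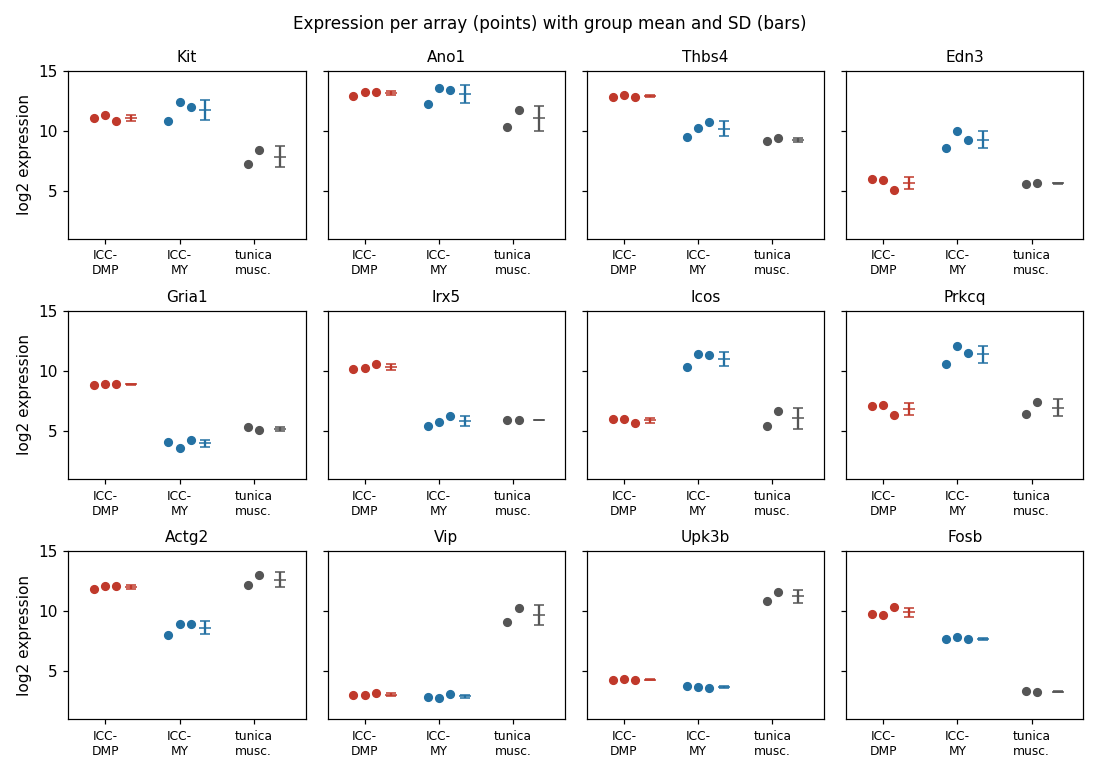
Log2 expression of 12 genes on each of the 8 arrays (points), with the mean and SD of each group beside them. Kit and Ano1 are high in both ICC classes, Gria1 (8.87 ± 0.04) and Irx5 (10.34 ± 0.23) in ICC-DMP alone, Icos (11.02 ± 0.59) and Edn3 (9.26 ± 0.72) in ICC-MY alone, and Actg2 is low in ICC-MY alone (8.62 ± 0.55).

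Among the largest differences, the genes higher in ICC-DMP included the BMP receptor gene Bmpr1b (4.71, SE 0.24), the BMP target Id1 (4.65, SE 0.21), the BMP antagonist genes Bmper (4.49, SE 0.20) and Grem1 (4.46, SE 0.31), and the Wnt inhibitor gene Wif1 (4.72, SE 0.21). The anion transporter gene Slc26a7 (4.81, SE 0.27) and the synaptic gene Snap91 (4.62, SE 0.27) completed the 10 largest of the ranked genes. Higher in ICC-MY, besides those above, were Sgpp2 (-5.12, SE 0.27), Tafa2 (-5.10, SE 0.33), Pcdh17 (-5.10, SE 0.33), the adhesion gene Vcam1 (-5.03, SE 0.35), Ctxn3 (-4.78, SE 0.35), Ampd3 (-4.77, SE 0.26) and Tmem178 (-4.74, SE 0.43). With tissue as a further reference, 344 genes were higher in ICC-DMP than in both other groups and 333 were higher in ICC-MY than in both. In turn, 141 were lower in ICC-DMP than in both and 532 lower in ICC-MY than in both.

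Of 10 ICC markers 5 were higher in ICC-MY, 6 adjusted over the list alone: Prkcq, Edn3 (-3.62, SE 0.37), Cacna1h (-3.33, SE 0.34), Slc12a2 (-2.44, SE 0.47, adjusted p = 0.0136) and Cd44 (-1.76, SE 0.27). Thbs4 was higher in ICC-DMP (2.71, SE 0.28), while Ano1 (0.06, SE 0.44), Gja1 (-0.17, SE 0.53), Kit (-0.65, SE 0.45) and Elovl6 (-1.27, SE 0.33) did not pass. The list had a median of -1.51 (adjusted p = 0.000262, but 0.554 with an estimated correlation and 0.0525 in fry) and is not independent evidence. Kit passed under quantile normalization (-0.91, adjusted p = 0.0167), with averaged probe sets (0.0422) and without the 2 narrow-range arrays (0.00851). Elovl6 passed under quantile normalization (-1.51, adjusted p = 0.000101), with the replicate block (-1.27, adjusted p = 0.0128), with dim probe sets removed (0.0335), with averaged probe sets (0.00741), with array weights (0.000678) and without the 2 narrow-range arrays (0.000155). The Slc12a2 call was lost without ICC-DMP replicate 1 or 3 (adjusted p = 0.0645 and 0.0584) and without ICC-MY replicate 3 (0.0533).

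Contractile genes were higher in ICC-DMP for 13 of 20 members, 17 adjusted over the list alone, such as Actg2 (3.38, SE 0.31), Myocd (3.24, SE 0.26), Myh11 (3.21, SE 0.40) and Synpo2 (3.18, SE 0.38). The list's median was 1.71 (adjusted p = 3.39e-16, and adjusted p = 0.182 with an estimated correlation). Acta2 (1.30, SE 0.38, adjusted p = 0.0867) did not pass, but did in 6 alternatives. These were quantile normalization (1.03, adjusted p = 0.00134), averaged probe sets (0.0117), array weights (0.0238), the replicate block (0.00202), the 2 narrow-range arrays left out (0.0134) and only the groups compared (0.0455). Immediate early genes were higher in ICC-DMP for 15 of 20 members, 19 adjusted over the list alone, including Ccn1 (2.84, SE 0.20), Btg2 (2.46, SE 0.27), Klf6 (2.31, SE 0.37) and Nr4a1 (2.25, SE 0.25). The list's median was 1.55 (adjusted p = 1.13e-16, and adjusted p = 0.123 with an estimated correlation). Gap junction and adhesion genes were higher in ICC-DMP for 5 of 16 members, also when adjusted over the list alone (median 0.39, adjusted p = 0.000125, and adjusted p = 0.123 with an estimated correlation). Ncam1, Cadm1 (3.99, SE 0.27), Cdh13 (2.75, SE 0.15) and Alcam (2.52, SE 0.18) had the largest differences.

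Genes of calcium handling split between the classes. Of 22 members 6 were higher in ICC-DMP and 4 in ICC-MY, with the same counts adjusted over the list alone, and the list was not called (median -0.02, mean 0.36, adjusted p = 0.252). Pln, which encodes the inhibitor of the sarcoplasmic calcium pump (3.60, SE 0.27), the channel gene Trpc4 (2.60, SE 0.31) and the ryanodine receptor gene Ryr2 (2.40, SE 0.26) were higher in ICC-DMP, and Cacna1h in ICC-MY. Atp2a3, a calcium pump gene, was higher than tissue in both classes (2.80, SE 0.46 in ICC-DMP and 3.33, SE 0.46 in ICC-MY). Among 24 neurotransmitter and paracrine signalling genes 5 were higher in ICC-DMP (6 adjusted over the list alone) and 3 in ICC-MY, without a call for the list (median 0.08, adjusted p = 0.294). The prostaglandin receptor gene Ptger3 (3.23, SE 0.30) and the serotonin receptor gene Htr4 (2.74, SE 0.13) were higher in ICC-DMP. Higher in ICC-MY were the PACAP receptor gene Adcyap1r1 (-3.37, SE 0.27) and the phosphodiesterase gene Pde3a (-2.70, SE 0.17). Tacr1, the substance P receptor gene that has served to mark ICC-DMP, averaged 4.34 ± 0.16 (n = 3) in ICC-DMP and 4.08 ± 0.18 (n = 2) in tissue, near the array medians. It did not differ in any comparison (0.14 between the classes, SE 0.14). Tacr3 (4.17 ± 0.10, 4.32 ± 0.15 and 4.30 ± 0.12) and Chrm3 (3.14 ± 0.17, 3.03 ± 0.21 and 3.25 ± 0.33) were near or below these levels. With its probe sets averaged, however, Tacr3 was lower than tissue in ICC-DMP (-1.30, adjusted p = 0.000448) and in ICC-MY (-1.32, adjusted p = 0.000342).

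Kcnk3, a background potassium channel gene, was higher in ICC-MY (-4.33, SE 0.35), while Kcnq5 was higher in ICC-DMP. Of 21 potassium and chloride channel genes 2 were higher in ICC-DMP and 1 in ICC-MY (3 and 2 adjusted over the list alone), and the list was not called (median 0.08, adjusted p = 0.298), except in fry (0.0274). MAPK feedback genes had 3 members higher in each class, or 3 in ICC-DMP and 4 in ICC-MY adjusted over the list alone (median 0.02, adjusted p = 0.748). Dusp4 (3.09, SE 0.37) and Ccnd1 (2.86, SE 0.31) were on the ICC-DMP side, Spry1 (-2.98, SE 0.28) and Phlda1 (-1.27, SE 0.19) on the other. Basement membrane and matrix genes were higher in ICC-DMP for 5 of 23 members (6 adjusted over the list alone) and in ICC-MY for 1 (median 0.18, adjusted p = 0.0939, and 0.0436 without ICC-MY replicate 2). Col4a5 (3.56, SE 0.37) and Mmp2 (2.18, SE 0.33) differed most. Hk2 (3.18, SE 0.19) was higher in ICC-DMP, as were 3 of 17 glycolysis and hypoxia genes in all (4 adjusted over the list alone), against 1 higher in ICC-MY (median -0.19, mean 0.23, adjusted p = 0.396). Oxidative phosphorylation genes passed as a list on the ICC-MY side (median -0.48, adjusted p = 0.000762, and adjusted p = 0.716 with an estimated correlation), with 0 of 29 members called by limma and 3 at an unadjusted p under 0.05. It was not called in fry (adjusted p = 0.42) and without ICC-MY replicate 2 (0.0742). Endothelial markers had 4 of 12 members higher in ICC-MY (5 adjusted over the list alone), such as Esam (-2.07, SE 0.33), and 1, Plvap (2.97, SE 0.23), higher in ICC-DMP (median -0.43, adjusted p = 0.00629, and adjusted p = 0.598 with an estimated correlation), a call lost in fry (0.177), without the 2 narrow-range arrays (0.0719) and without ICC-MY replicate 1 (0.0508).

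**Figure D3:**
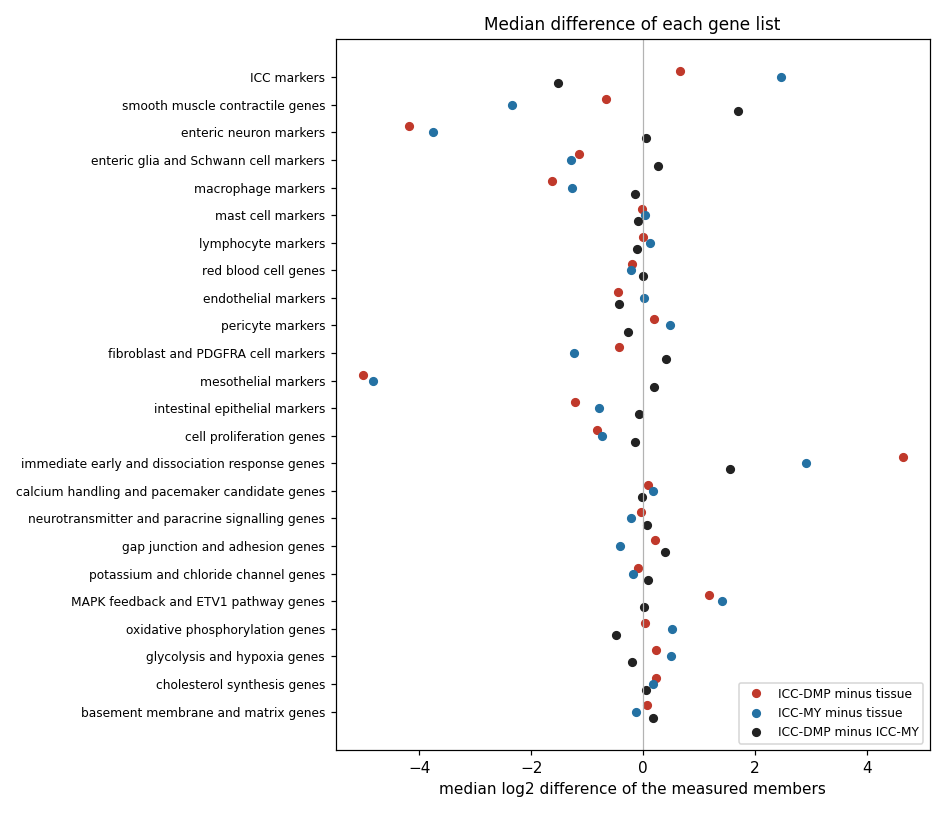
Median log2 difference of the measured members of each of the 24 gene lists for ICC-DMP minus tissue, ICC-MY minus tissue and ICC-DMP minus ICC-MY. Neuron (-4.19 and -3.75) and mesothelial markers (-5.02 and -4.83) are low in both classes, while contractile genes (-0.66 and -2.35) and immediate early genes (4.64 and 2.91) separate the classes. Between the classes these last 2 lists passed camera with the preset correlation but not with an estimated one (adjusted p = 0.182 and 0.123).

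Markers of neurons, mesothelium and macrophages did not differ as lists between the 2 classes. Neuron markers had 3 of 19 members higher in ICC-MY, also when adjusted over the list alone, including Ret (-1.46, SE 0.19) and Elavl3 (-1.32, SE 0.13). The list was not called (median 0.06, mean -0.17, adjusted p = 0.257). For macrophage markers limma called 0 of 16 members, 1 at an unadjusted p under 0.05 (adjusted p = 0.104 for the list). Mesothelial markers had 1 of 10 members higher in ICC-MY, and adjusted over the list alone 2 were higher in ICC-DMP and 1 in ICC-MY (adjusted p = 0.332 for the list).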

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

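Every test in this part except the regrouping of the ICC arrays was chosen after the results were seen. The genes that stood in opposite directions to tissue in the 2 ICC classes drew attention first: 80 were higher in ICC-DMP and lower in ICC-MY, and 23 the reverse. Among the named genes, those on the ICC-DMP side were Gria1 (4.92 between the classes), Slc26a7 (4.81), Wif1 (4.72), Bmpr1b (4.71), Id1 (4.65), Grem1 (4.46), Ncam1 (4.02), Pln (3.60), Hk2 (3.18) and Htr4 (2.74). On the ICC-MY side they were Dsp (-5.24), Sgpp2 (-5.12), Tafa2 (-5.10), Vcam1 (-5.03), Ampd3 (-4.77) and Ednrb (-1.86). Each of these differences passed in the direct comparison, but passing it was a condition for choosing these genes and so is no separate support. For Ednrb the decrease against tissue in ICC-DMP (-0.86, adjusted p = 0.0426) was lost without each ICC-DMP replicate, without ICC-MY replicate 3 and without each tissue replicate, with adjusted p between 0.0612 and 0.19. It was also lost with arrays centred on their medians (0.0547), averaged probe sets (0.104), trend and robust settings (0.136) and array weights (0.081).

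Much of the array was left unnamed. Among probe sets absent from the annotation, 641 of 9160 passed between the ICC classes (494 higher in ICC-DMP and 147 in ICC-MY) and 1421 passed between the ICC mean and tissue (1249 higher and 172 lower in ICC). Of 932 probe sets naming several genes, 33 and 100 passed in these comparisons. The excess of unnamed probe sets on the ICC side is not explained here.

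Immediate early genes were higher in ICC-DMP than in ICC-MY by a median of 1.55. A response to isolation of equal size in both classes would put that median near 0 with no call, and 15 of 20 members were called, 19 adjusted over the list alone. The SE over members was 0.14, but it counts members as independent, and their estimated correlation was 0.41. These values are the observation that raised the question, so they are not a separate test of an equal response. The set test with an estimated correlation, which the bound written for this explanation also asked for, did not pass (adjusted p = 0.123). The narrow range of ICC-MY replicate 1 is not the cause: without the 2 narrow-range arrays the median was 1.40 (SE over members 0.16, adjusted p = 7.17e-14 by camera with the preset correlation). Handling that differed between the classes remains possible, since all ICC-DMP arrays lay above all ICC-MY arrays for 19 of 20 members (chance share 5%), and class and isolation coincide in every array.

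Contractile genes of ICC-DMP were closer to the tissue level than those of ICC-MY, which could come from carried-over muscle RNA or from expression by the cells. For the 16 contractile genes that were lower in ICC-MY than in tissue, the part of the distance from ICC-MY to tissue that ICC-DMP covered, on the linear scale, was 9.64% (Des) to 82.1% (Tpm2), with a median of 50.5%. These shares include the 2 narrow-range arrays, which read low at high levels, and were not recomputed without them. Without those arrays the difference of ICC-DMP to tissue went from -0.80 to -1.60 for Myh11 and from -0.61 to -1.04 for Actg2. Of the 16 genes, 2 deviated from their common difference to tissue, Des (by -1.06, SE 0.26, adjusted p = 0.0304) and Cnn1 (by -0.69, SE 0.13, adjusted p = 0.0149). They are fewer than the bound set for excluding 1 common share of muscle RNA asked for. Such a share gives equal log2 differences only where ICC-MY holds almost none of a gene's transcript, so the deviations do not test it directly. Cnn1 (31.1% of the distance) deviated, while Casq2 (31.8%) did not (adjusted p = 0.0919). Over all 20 members 7 deviated, 3 of them among the genes not lower in ICC-MY, for which carry-over predicts no common difference. Over 45 neuron, mesothelial and macrophage genes the median difference between the classes was -0.046 (SD over genes 0.44). By limma 0 were higher and 4 lower in ICC-DMP (2 and 5 at an unadjusted p under 0.05), so carry-over of these 3 cell types does not account for it. Fibroblast and glia lists leaned to ICC-DMP without a camera call in the main fit (medians 0.41 and 0.27, adjusted p = 0.153 and 0.0923), each with 2 members higher and 0 lower. The glia list was called as higher in ICC-DMP in fry (adjusted p = 0.00676). Camera called it too with averaged probe sets (adjusted p = 0.0273) and without ICC-MY replicate 1 (0.0408). Endothelial and pericyte markers leaned to ICC-MY (medians -0.43 and -0.27). Carry-over of muscle cells, alone or with fibroblasts or glia, remains possible, and a sort that would remove them is not given in the sources used here.

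Icos and Ms4a4b, both known from T cells, were higher in ICC-MY by 5.14 and 4.41 (SE 0.37 and 0.15); Ms4a4b was named after its values were seen. Carried-over lymphocyte RNA would raise other lymphocyte genes as well, but the list's median difference was 0.12 and 0 of 10 members passed in limma, with 0 at an unadjusted p under 0.05. The most abundant members, Cd8a (6.90 in ICC-MY and 6.19 in ICC-DMP) and Cd3e (5.51 and 5.10), did not pass. Their differences towards ICC-MY, 0.71 (SE 0.84) and 0.41 (SE 0.32), were far smaller than that of Icos. Other members such as Cd3g (2.68 in ICC-MY) and Cd2 (2.91) read low, so they say little. An unspecific probe set of Icos is not the cause either, since 3 of 3 Icos probe sets were higher in ICC-MY (by 4.09, 3.35 and 5.14).

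The 6 ICC arrays can be split 3 against 3 in 10 ways, too few for a share under 0.05. The real split gave 1577 genes and is the 1 of the 10 with that many; the highest other split gave 0 in limma. Since same-numbered arrays varied together, the closest comparison is with the 4 splits that part all 3 same-numbered pairs. Among these the others had at most 268 genes at an unadjusted p under 0.05, against 3360 for the real split. The splits that keep 2 pairs together reached up to 1029, and they also set pairs against each other. Every split but the real one mixes both classes in each arm, so the class difference adds to the spread within arms. Their low counts follow in part from this construction and give no chance level.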

How the results depend on the processing

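The cells and tissue were compared on 8 arrays, whose signals saturate at high and flatten at low levels, so folds of very dim or very bright genes are understated. In the order ICC-DMP against tissue, ICC-MY against tissue, ICC-DMP against ICC-MY and the ICC mean against tissue, the main counts were 2009, 2516, 1577 and 2366. They became 3126, 3904, 2558 and 3745 under quantile normalization, 5657, 5691, 3335 and 6128 with every probe set counted (the unit then is not the gene), and 1094, 1468, 921 and 1297 at a threshold of 0.01. Between the ICC classes, array weights gave 2646 (1358 higher and 1288 lower in ICC-DMP), the replicate block 2617 (2853, 3537 and 3191 in the others, in that order), and leaving out the 2 narrow-range arrays, chosen after the data were seen, 2630. Fitting only the groups compared gave 1520 for ICC-MY against tissue; for the ICC mean that setting uses all 3 groups anyway and has no separate value. Leaving out 1 array at a time gave 1264 to 2480, 1965 to 2960, 991 to 1840 and 1747 to 2971. The number of genes shared by both comparisons with tissue, 1254 in the same direction, was 696 at a threshold of 0.01 and 839 to 1451 with 1 array left out. Of 45 list calls 9 remained with an estimated correlation. In fry 30 remained, 15 were lost and 4 others gained, and 42 to 49 of the 96 list tests were called with 1 array left out. The cause of these moves was not tested, except that a stricter threshold, a larger number of probe sets and fewer arrays in the fit move a count by construction.

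Where a tissue array was left out, the remaining 1 was assumed to vary like the other groups. Without ICC-MY replicate 1, 872 genes were higher and 968 lower in ICC-DMP than in ICC-MY, so that array carries much of the imbalance between the classes. Of 410 named results 310 had the same outcome as in the main fit in each of the 17 alternatives run for them. An outcome here is called or not called, so the 310 include results that passed nowhere. Removing dim probe sets covered 396 of the 410, and fitting only the groups compared 283. Direction turned in 3 results that had not been called: without the 2 narrow-range arrays, oxidative phosphorylation genes in ICC-DMP against tissue (lower, adjusted p = 0.048) and Cd8a in the ICC mean against tissue (1.25), and Tacr3 in ICC-MY against tissue with a gene's probe sets averaged (-1.32). The replicate block also gave calls to glycolysis and hypoxia genes (adjusted p = 0.034), Acta2 (0.0354), Ptger3 (0.0152) and Slc12a2 (0.0445) in the ICC mean and to Cacna1h in ICC-DMP against tissue (-1.07, adjusted p = 0.0106), and among the named genes and lists it changed no other call besides those given with the results.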

Other observations

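In a screen of gene families by symbol stem, made after the results were seen, some voltage-gated sodium channel genes were lower in the ICC classes than in tissue. Enteric neuron markers were lower as well (18 of 19, median -4.09), so loss of neurons is an open explanation. In that screen 6 family tests passed, and 0 with an estimated correlation. Of 11 Scn genes 7 were lower in the ICC mean, with Scn9a (-4.21, SE 0.14), Scn3b (-3.74, SE 0.12), Scn11a (-2.85, SE 0.29) and Scn3a (-2.45, SE 0.24) the largest, and the family's median was -1.69 (adjusted p = 0.000463 over 610 family tests, and adjusted p = 0.996 with an estimated correlation). Scn1a, Scn4b, Scn8a and Scn10a did not pass. Between the classes only Scn2b passed, higher in ICC-MY (-1.62, SE 0.21). The median was -1.69 under quantile normalization too, and -1.72 with arrays centred on their medians.

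In the same screen, 5 of 10 Hoxb genes and 5 of 16 Klf transcription factor genes were higher in ICC-DMP than in ICC-MY, and the others did not pass. Hoxb6 (2.14, SE 0.29), Hoxb3 (1.91, SE 0.24), Hoxb2 (1.87, SE 0.18), Hoxb5 (1.59, SE 0.30) and Hoxb4 (adjusted p = 0.00458) were the Hoxb members that passed (family median 0.74, adjusted p = 0.0169, and adjusted p = 0.996 with an estimated correlation). The Klf members were Klf2 (2.90, SE 0.21), Klf6 (2.31, SE 0.37), Klf4 (2.19, SE 0.29), Klf10 (2.09, SE 0.24) and Klf7 (0.88, SE 0.14), with a family median of 0.56 (adjusted p = 0.00194, and adjusted p = 0.996 with an estimated correlation). Under quantile normalization these medians were 0.61 and 0.44. Klf6 belongs to the immediate early list too, so some of these differences may share a source with that list, whose median stayed at 1.40 without the 2 narrow-range arrays.

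No list of BMP or Wnt genes was tested, and the genes named here were picked for their large differences. The BMP target Id1 was higher in ICC-DMP and the Wnt inhibitor gene Dkk2 in ICC-MY, also without the 2 narrow-range arrays (4.56 and -5.67). Whether BMP signalling differs between the layers stays open, since the antagonist genes Bmper and Grem1 were higher in ICC-DMP as well, and position and isolation cannot be separated on these arrays. Staining for phosphorylated SMAD in whole-mount muscle would test it, and so would Id1 in ICC of both layers without dissociation.

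The contractile transcripts of ICC-DMP might mark a cell intermediate between muscle and ICC, or muscle cells carried along. The 2 genes of 16 that deviated from a common difference to tissue, Des and Cnn1, do not decide between them. Single-cell sequencing would: co-expression of Kit with Actg2 in single cells favours the former, and separate Kit-negative Actg2 cells the latter. Isolation with an inhibitor of transcription would likewise test how much of the immediate early difference, seen without overlap in 19 of 20 members, arose after dissection.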
